A study of Glycine max with 12 samples.

How the data were processed

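RNA was measured in soybean (Glycine max) seeds at a stage the labels call H3. What H3 stands for is not given in the sources used here. There were 12 libraries, 3 from the wild type, labelled Jack, and 3 from each of 3 overexpressor genotypes, labelled transgenic soybean and named for GmZF351, GmZF392 and GmNFYA. Per the labels, total RNA was extracted with TRIzol and sequenced from Illumina libraries. The labels number the libraries of each genotype 1 to 3 and do not say whether each came from a separate plant, so p-values measure the spread between these samples, which may be technical. The titles of an overexpressor's libraries share a code, so all 3 may come from a single transgenic line. Effects of such a line could not be told apart from those of the overexpressed gene.

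Per the file headers, the authors' deposited table holds raw counts per gene from featureCounts 2.0.1, made with paired-end fragments, exon features summed by gene, and the annotation Gmax_508_Wm82.a4.v1. The recorded command names no option for strand, multimapping reads or overlapping genes, so the counts of close paralogs depend on how uniquely their fragments aligned. The submitters' processing notes also name HISAT2 and DESeq2 without versions. The deposited table also gives each gene's exon length, used here only for a trend between libraries. The reads themselves were not analysed here.

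The table holds 47095 genes. Gene names were taken from RefSeq genes of the Williams 82 assembly Glycine_max_v4.0, by pairing each gene with the RefSeq protein-coding gene whose span overlapped it by at least 50% of the union of both spans; 38244 genes (81.2%) were paired, and 38.8% of the pairs matched at both ends within 100 bp. Of the paired genes, 2199 have a symbol. RefSeq symbols were used to name genes and to form the gene lists and symbol families, and the counts do not depend on them. Gene identifiers are printed without the annotation suffix, and positions are those of the deposited table. The GmZF351 and GmZF392 loci were assigned from knowledge of the study, to be used if the annotation described them as CCCH zinc finger genes. The tables used here give no such description, so their identity rests on that knowledge and on their counts; the GmNFYA locus carries the RefSeq symbol NF-YA02. Counts do not separate fragments of a transgene from those of the endogenous gene.

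Libraries held 17809547 to 22652420 counted fragments and 38267 to 39478 genes with at least 1 fragment. The 10 most abundant genes took 3.4% to 4.6% of a library, and SSTP-1 was the most abundant gene in each (0.70% to 1.59%). A count of 0 allows up to 3 counts, which is 0.132 to 0.168 CPM (counts relative to the scaled library total); this covers counting error only. CPM values are given as mean ± SD of 3 libraries, scaled by TMM factors, and log2 fold changes with their standard error (SE).

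Differences were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, robust quasi-likelihood F-test, filterByExpr with a minimum count of 10 and a minimum total of 15), with all 12 libraries in 1 fit and 1 coefficient per genotype. This left 34252 genes, and the Benjamini-Hochberg threshold was 0.05. Each overexpressor was compared with the wild type and with each other overexpressor, and 1 test covered all 4 genotypes. "Rose" and "fell" are used of genes past this threshold. An exact test of a single gene in 3 against 3 libraries cannot give a p below 0.1. The test was tried on simulated counts with 200 genes changed among 33915. It recovered 66 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and 10 of the 174 called were unchanged. In a separate simulation 1 list was shifted 2-fold and a trend with exon length was imposed on the libraries. There 2 gene lists were called, of which 1 had been shifted.

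Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with the inter-gene correlation preset at 0.01, and again with an estimated correlation; lists needed 5 tested members, and p-values were adjusted over the lists. List counts "adjusted over the list alone" use the edgeR p-values of its members. Symbol families with at least 8 tested genes were tested for enrichment among rising and falling genes with a one-sided Fisher's exact test (35 families, background 1689 tested genes with a symbol). Their p-values were adjusted over the families within each comparison and direction, and the test treats the genes of a family as independent. A family here holds only the tested genes that carry its symbol, so members without a symbol were not counted. Fold changes against the same wild-type libraries were compared through their covariance and that of 20 simulations of unchanged groups.

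The comparisons, tests, thresholds, alternatives and naming rule, and 30 gene lists defined by product name, were chosen before the data were examined. The annotation used here gives symbols in place of product names, so after the table was seen and before any test the lists were rewritten by symbol as 28 lists. Of these, 22 keep the name of an earlier list and 6 have another name, of which 4 (aquaporins, seed coat, nodule, clock) were added; 8 of the first kind were not kept under the same name, of which 5 (starch, CCCH zinc fingers, ribosomal proteins, lipid-transfer proteins, organelle-encoded genes) were not rewritten. Product families were replaced by symbol families in the same way. The 28 lists cover fatty acid synthesis, desaturases, triacylglycerol assembly and oil bodies, oil regulators (LEC1, ABI3, ABI5, WRI1, AGL15), glycolysis and PEP carboxylase, sugar transport, lipid breakdown, storage proteins, protease inhibitors, lipoxygenases, late embryogenesis, NF-Y subunits, photosynthesis, flavonoids, lignin, cell cycle, heat shock, pathogenesis, jasmonate, abscisic acid, gibberellin, auxin, cell wall, endoplasmic reticulum folding, aquaporins, seed coat, nodule and clock genes.

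Genes were named by a rule. For each overexpressor against the wild type it took the 8 rising and 8 falling genes with the largest fold change among those past the threshold with a symbol, an average log2 CPM of 1 or more and no overlap between the groups' libraries. To these it added up to 4 called members of each list that was called or had 3 or more called members. It also added the 2 most expressed members of the oil regulator, desaturase, triacylglycerol and oil body, and storage lists whether called or not. Between overexpressors it took 5 genes in each direction, and for enriched families up to 3 members. Not all are printed. SWEET4, FAD8.2, CRK48 and CRK62, P34 and FAD2-1A in the GmZF392 overexpressor, and the genes printed by identifier other than the overexpressed ones were chosen after their values were seen.

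Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, a threshold of 0.01, fits of only the 6 libraries compared, the replicate number as a block, an estimated correlation for lists, and leaving out each library in turn. Added after the data were seen were offsets that remove each library's trend with exon length (lowess, span 0.3), leaving out both libraries at the ends of that trend, leaving out each library from the test of 4 genotypes, and leaving out genes that differ by a log2 of 3 or more in all 3 overexpressors. The replicate numbers showed no consistent pairing of the libraries. Residual correlations between libraries with the same number ran from -0.50 to 0.42 over 18 pairs, 7 of them above 0.1. Of 12 libraries, 5 matched best a library of their own number. With 3 libraries per genotype this cannot exclude a pairing. Effects of GC content were not analysed here.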

Results

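The 12 libraries compare soybean seeds that overexpress either of a pair of zinc finger genes, or a nuclear factor Y subunit, with wild-type seeds. All these genes are known as regulators of seed oil. Expression is given as the mean of 3 libraries in CPM ± SD (n = 3). The adjusted p of a gene is from the edgeR fit of 34252 genes unless another fit, test or set of libraries is named, and that of a gene list is from camera.

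Each overexpressed gene had its highest expression in its own genotype. GmZF351 (Glyma.06G290100, chromosome 6, 47496646 to 47498247, minus strand) stood at 936 ± 63.1 CPM in the GmZF351 overexpressor and 18.7 ± 1.6 CPM in the wild type, 50.1-fold higher (log2 5.65, SE 0.16, adjusted p = 4.1e-10). GmZF392 (Glyma.12G205700, chromosome 12, 38059961 to 38061812, plus strand) stood at 648 ± 95.7 CPM in its overexpressor and 70.3 ± 1.86 CPM in the wild type, 9.21-fold higher (log2 3.20, SE 0.17, adjusted p = 2.4e-07). GmNFYA (NF-YA02, Glyma.02G303800, chromosome 2, 49719199 to 49723036, minus strand) stood at 308 ± 35.1 CPM in its overexpressor and 41.8 ± 1.41 CPM in the wild type, 7.37-fold higher (log2 2.88, SE 0.15, adjusted p = 1.1e-07). GmZF351 was also 2.13-fold higher in the GmZF392 overexpressor than in the wild type, at 39.9 ± 1.92 CPM (log2 1.09, SE 0.14, adjusted p = 4.3e-04). In the GmNFYA overexpressor it stood at 26.9 ± 1.35 CPM, a difference that did not pass the threshold (log2 0.53, SE 0.14, adjusted p = 0.0836). It passed with the DESeq2 Wald test (7.4e-04) and with exon-length offsets (0.0123). The adjusted p ran up to 0.313 over the alternatives, the value without wild-type library 2. GmZF392 did not pass the threshold in the GmZF351 overexpressor (86 ± 8.24 CPM, adjusted p = 0.53) or the GmNFYA overexpressor (92.7 ± 12.9 CPM, adjusted p = 0.335). GmNFYA stood at 40.9 ± 3.45 CPM and 45.6 ± 3.57 CPM in the GmZF351 and GmZF392 overexpressors and did not pass there (adjusted p = 0.969 and 0.789).

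**Figure D1:**
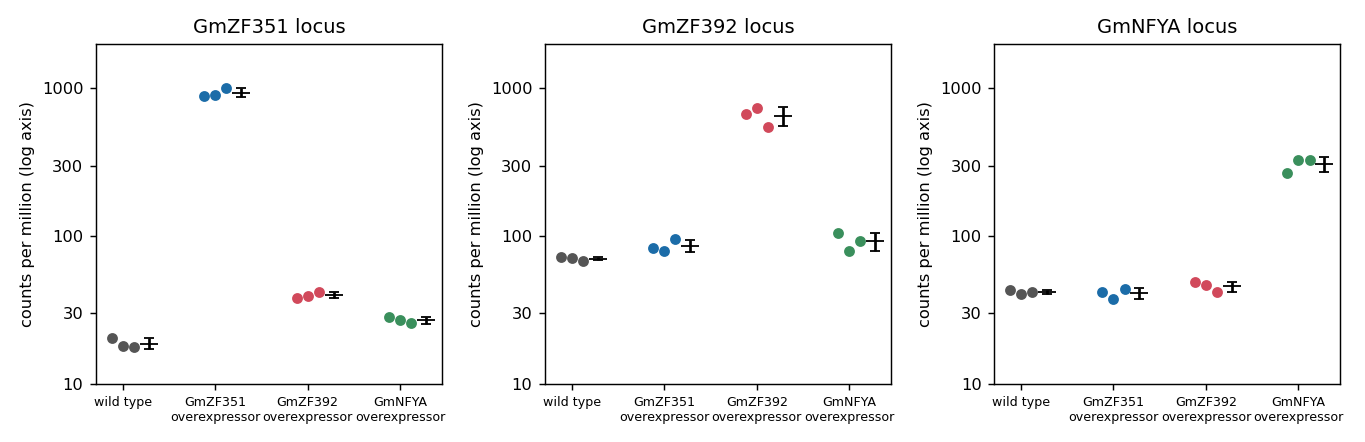
CPM (log axis) of GmZF351, GmZF392 and GmNFYA in the 12 libraries by genotype; each point is 1 library, with mean and SD beside the 3 points. Each gene is highest in its own overexpressor (936, 648 and 308 CPM), and GmZF351 is also above the wild type (18.7 CPM) in the GmZF392 overexpressor (39.9 CPM).

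In the GmZF351 overexpressor 7 of 13 tested storage protein genes rose against the wild type, among them GY1, GY2 and GY4 for glycinins, which are the 11S seed storage globulins. GY1 rose 6.23-fold, from 34.6 ± 6.73 to 216 ± 76 CPM (log2 2.64, SE 0.27, adjusted p = 1.0e-04). GY2 rose 4.95-fold (log2 2.31, SE 0.16, adjusted p = 4.4e-06) and GY4 5.88-fold (log2 2.56, SE 0.21, adjusted p = 1.5e-05). The conglycinin gene CG-1 rose 2.95-fold, from 591 ± 24 to 1740 ± 57.9 CPM (log2 1.56, SE 0.13, adjusted p = 2.1e-05). P34, which encodes a seed vacuolar protein and allergen, rose 3.36-fold (log2 1.75, SE 0.16, adjusted p = 4.7e-05). The seed lipoxygenase genes LOX2 (log2 2.53, SE 0.21, adjusted p = 1.7e-05) and LOX3 (log2 1.39, SE 0.14, adjusted p = 1.1e-04) rose, as did the Kunitz trypsin inhibitor gene KTI1 (log2 2.19, SE 0.25, adjusted p = 2.4e-04). LAR1, for leucoanthocyanidin reductase, an enzyme of proanthocyanidin synthesis, fell 8.44-fold from 180 ± 16 to 21.3 ± 1.7 CPM (log2 -3.08, SE 0.15, adjusted p = 1.4e-07). The sugar transporter genes SWEET17 (log2 -2.59, SE 0.20) and SWEET16 (log2 -2.25, SE 0.17) fell, both with an adjusted p of 8.9e-06, and so did the vegetative storage protein gene VSPA, 3.32-fold (log2 -1.73, SE 0.13, adjusted p = 8.9e-06). The chaperone genes HSP90A1 (log2 -3.01, SE 0.32, adjusted p = 1.6e-04), HSP23.9 (log2 -1.52, SE 0.17, adjusted p = 2.9e-04) and HSP90A2 (log2 -1.33, SE 0.21, adjusted p = 0.00325) fell too.

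In the GmZF351 overexpressor 1 of 18 desaturases rose and 1 fell (3 and 4 adjusted over the list alone). Of 7 triacylglycerol assembly and oil body genes 2 rose (2 rose and 1 fell adjusted over the list alone), and neither list was shifted (adjusted p = 0.656 and 0.717). FAD2-1B, a seed oleate desaturase gene, rose from 185 ± 9.98 to 312 ± 31.2 CPM (log2 0.75, SE 0.13, adjusted p = 0.00851); the call ended without GmZF351 overexpressor library 3 (adjusted p = 0.053, with 3.9e-10 the lowest over the alternatives). The desaturase gene FAD8.2 fell from 48.6 ± 4.44 to 30.4 ± 3.14 CPM (log2 -0.68, SE 0.14, adjusted p = 0.0183). Its call ended without wild-type library 1 (adjusted p = 0.0811), 2 (0.0523) or 3 (0.0515) or overexpressor library 2 (0.0685) or 3 (0.0602), with 2.9e-04 the lowest over the alternatives. The oleosin genes P91, from 680 ± 291 to 1820 ± 419 CPM (log2 1.42, SE 0.32, adjusted p = 0.0357), and P89, from 658 ± 297 to 1580 ± 47.6 CPM (log2 1.27, SE 0.30, adjusted p = 0.0459), rose. The P91 call ended without wild-type library 1 (adjusted p = 0.084), 2 (0.0593) or 3 (0.0768) and without overexpressor library 2 (0.101) or 3 (0.0864), with 4.3e-04 the lowest over the alternatives. The P89 call ended without any of the wild-type libraries (0.0555, 0.0625 and 0.0797) or the overexpressor libraries (0.0845, 0.0876 and 0.13), with 0.00111 the lowest. The embryo regulator LEC1-B (358 against 329 CPM, log2 0.12, adjusted p = 0.825) did not pass. PPCK2, for a kinase of PEP carboxylase, rose from 38.2 ± 4.79 to 76.5 ± 7.66 CPM (log2 1.0, SE 0.13, adjusted p = 8.0e-04).

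By gene list, 8 lists were shifted in the GmZF351 overexpressor. Storage proteins were shifted up (13 members, median log2 1.56, 7 higher, 9 adjusted over the list alone; adjusted p = 6.2e-16, and adjusted p = 4.9e-04 with an estimated correlation). Also up were protease inhibitors (7 members, median log2 0.93, adjusted p = 1.5e-07), late embryogenesis genes (28 members, median log2 0.77, adjusted p = 2.3e-07), lipoxygenases (8 members, median log2 0.20, adjusted p = 0.00334) and glycolysis with PEP carboxylase, called glycolysis below (10 members, median log2 0.19, adjusted p = 0.0122). With an estimated correlation these gave adjusted p = 0.169, 0.417, 0.417 and 0.169. Shifted down were heat shock genes (16 members, median log2 -0.19, adjusted p = 0.00251), seed coat markers (5 members, median log2 -0.29, adjusted p = 0.00292) and photosynthesis genes (13 members, median log2 -0.20, adjusted p = 0.00334). These gave adjusted p = 0.571, 0.169 and 0.276 with an estimated correlation. Lipoxygenases were called in 5 of the 6 fits that each leave out 1 library, and the other lists in all 6.

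Against the wild type, 744 genes differed in the GmZF351 overexpressor, 386 higher and 358 lower, and 429 of them by 2-fold or more. The libraries of both groups did not overlap for 16.5% of tested genes. Splits of 6 libraries average 10% by construction, and single splits can differ from that, so the excess is not a test of genotype. The count was 442, 394 and 392 without wild-type library 1, 2 or 3 and 404 without overexpressor library 3, and it rose to 1329 with exon-length offsets.

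In the GmZF392 overexpressor 7 of the 13 storage protein genes rose against the wild type. GY4 rose 20.8-fold to 40.6 ± 7.74 CPM (log2 4.38, SE 0.21, adjusted p = 9.4e-08) and GY1 9.07-fold to 314 ± 71.8 CPM (log2 3.18, SE 0.27, adjusted p = 1.5e-05). GY2 rose 7.53-fold to 211 ± 21 CPM (log2 2.91, SE 0.17, adjusted p = 4.6e-07) and CG-1 3.95-fold to 2340 ± 113 CPM (log2 1.98, SE 0.14, adjusted p = 2.2e-06). KTI1 rose 13.1-fold (log2 3.71, SE 0.25, adjusted p = 2.2e-06). The lipoxygenase genes LOX2 (log2 2.48, SE 0.21, adjusted p = 1.5e-05), LOX3 (log2 1.76, SE 0.14, adjusted p = 9.1e-06) and LOX1.1 (log2 1.42, SE 0.23, adjusted p = 0.00353) rose. P34 rose to 316 ± 30.8 CPM (log2 1.72, SE 0.16, adjusted p = 3.5e-05). GH3, of a family that conjugates auxin, rose 7.22-fold (log2 2.85, SE 0.28, adjusted p = 4.9e-05). The transcription factor gene LBD30 rose to 6.62 ± 1.1 CPM (log2 2.56, SE 0.34, adjusted p = 6.7e-04). NAC transcription factor genes with a symbol were enriched among the genes that rose, with 6 of 18 such genes tested, against the background of tested genes with a symbol (one-sided Fisher's exact test, adjusted p = 0.00228). Among them were NAC27 (log2 2.30, SE 0.30), NAC018 (log2 1.97, SE 0.26) and NAC2 (log2 1.03, SE 0.12).

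Both seed oleate desaturase genes rose in the GmZF392 overexpressor. FAD2-1B rose 2.03-fold to 376 ± 19.1 CPM (log2 1.02, SE 0.13, adjusted p = 6.7e-04). FAD2-1A rose from 20.6 ± 2.19 to 46.2 ± 7.19 CPM (log2 1.17, SE 0.16, adjusted p = 9.2e-04). P91 stood at 1360 ± 112 CPM (log2 1.0, SE 0.32, adjusted p = 0.172) and P89 at 1410 ± 69 CPM (log2 1.1, SE 0.30, adjusted p = 0.0908). Neither oleosin gene passed the threshold, but both did with the replicate number as a block (0.0401 and 0.0396), with exon-length offsets (0.0404 and 0.0373) and with the DESeq2 Wald test (0.0461 and 0.00861). Over the alternatives the adjusted p ran from 0.0401 to 0.337 for P91 and from 0.00861 to 0.247 for P89. ABI5, a regulator of abscisic acid response, rose (log2 0.97, adjusted p = 0.019). The call ended without wild-type library 1 (0.0863) or 2 (0.0921) or overexpressor library 1 (0.0522), 2 (0.0746) or 3 (0.0543), with 7.7e-04 the lowest over the alternatives. LEC1-B (log2 0.14, adjusted p = 0.751) and the stearoyl desaturase gene SACPD-C (log2 0.33, adjusted p = 0.701) did not pass. LAR1 fell 7.2-fold to 24.9 ± 3.17 CPM (log2 -2.85, SE 0.15, adjusted p = 2.4e-07). SWEET16 (log2 -1.66, SE 0.17, adjusted p = 6.7e-05), SWEET17 (log2 -1.32, SE 0.18, adjusted p = 9.9e-04) and SWEET5 (log2 -0.88, SE 0.15, adjusted p = 0.00525) fell. This made the SWEET family enriched among falling genes (3 of 24, one-sided Fisher's exact test, adjusted p = 0.0496). That value lies close to the threshold, and the sugar transport list was not shifted in this comparison (camera, adjusted p = 0.866). HSP90A1 (log2 -1.84, SE 0.30, adjusted p = 0.00353), HSP23.9 (log2 -1.20, SE 0.17, adjusted p = 0.00132) and HSP90A2 (log2 -1.15, SE 0.21, adjusted p = 0.0069) fell, 3 of 14 tested genes with an HSP symbol (one-sided Fisher's exact test, adjusted p = 0.0193).

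By gene list, 8 lists were shifted in the GmZF392 overexpressor. Storage proteins were shifted up (median log2 1.31, 7 higher, 12 adjusted over the list alone; adjusted p = 7.9e-19, and adjusted p = 2.6e-04 with an estimated correlation). Protease inhibitors (median log2 0.71, adjusted p = 5.3e-06), late embryogenesis genes (median log2 0.41, adjusted p = 5.3e-06), lipoxygenases (median log2 0.11, adjusted p = 0.0204), lipid breakdown genes (median log2 0.32, adjusted p = 0.0382) and glycolysis (median log2 0.12, adjusted p = 0.0384) were shifted up. With an estimated correlation they gave adjusted p = 0.262, 0.465, 0.465, 0.262 and 0.262. Heat shock (median log2 -0.43, adjusted p = 0.00897) and cell wall genes (median log2 -0.28, adjusted p = 0.0355) were shifted down, with adjusted p = 0.57 and 0.662 with an estimated correlation. With exon-length offsets the lipoxygenase, lipid breakdown, glycolysis and cell wall calls ended (adjusted p = 0.0772, 0.077, 0.0748 and 0.0772), and the number of lists called was 3 without wild-type library 2 and 5 without overexpressor library 1 or 3. Of the 6 fits that each leave out 1 library, 5 called heat shock genes, 4 lipoxygenases, 3 cell wall genes and 2 each glycolysis and lipid breakdown.

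Against the wild type, 752 genes differed in the GmZF392 overexpressor, 571 higher and 181 lower, and 511 by 2-fold or more. The groups did not overlap for 17.9% of tested genes, where splits of 6 libraries average 10% by construction. The count was 448 without wild-type library 2, 477 without wild-type library 3, and 1192 with exon-length offsets.

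In the GmNFYA overexpressor 6 of the 13 storage protein genes rose and 5 of 24 tested sugar transporter genes with a SWEET symbol fell. The storage list gene A1 did not pass in any overexpressor (219 ± 63.5 CPM in the wild type and 305 ± 84, 373 ± 97.8 and 252 ± 22 CPM in the GmZF351, GmZF392 and GmNFYA overexpressors, adjusted p = 0.505, 0.193 and 0.782). GY4 rose 9.46-fold to 18.5 ± 2.27 CPM (log2 3.24, SE 0.21, adjusted p = 1.5e-06) and GY2 4.21-fold to 118 ± 4.34 CPM (log2 2.07, SE 0.16, adjusted p = 7.8e-06). GY1 rose 4.11-fold to 142 ± 4.11 CPM (log2 2.04, SE 0.26, adjusted p = 7.8e-04) and CG-1 2.97-fold to 1760 ± 56.8 CPM (log2 1.57, SE 0.13, adjusted p = 1.7e-05). KTI1 rose 10.7-fold (log2 3.42, SE 0.25, adjusted p = 4.7e-06). SWEET21 fell 4.13-fold from 64.1 ± 3.68 to 15.5 ± 1.67 CPM (log2 -2.05, SE 0.14, adjusted p = 2.6e-06). SWEET11 fell 2.60-fold from 60.7 ± 3.42 to 23.4 ± 0.814 CPM (log2 -1.38, SE 0.14, adjusted p = 1.2e-04) and SWEET15 1.89-fold from 20.1 ± 0.686 to 10.6 ± 0.902 CPM (log2 -0.92, SE 0.13, adjusted p = 0.00193). SWEET10 (log2 -0.94, adjusted p = 0.0346) and SWEET4 (log2 -0.79, adjusted p = 0.0496) fell as well, and the family was enriched among falling genes (one-sided Fisher's exact test, adjusted p = 7.0e-04). The SWEET10 call ended without any of wild-type libraries 1 to 3 (0.123, 0.149 and 0.0559) or overexpressor libraries 1 to 3 (0.129, 0.157 and 0.082), with 0.00218 the lowest adjusted p over the alternatives. The SWEET4 call ended without wild-type library 2 or 3 (0.22 and 0.169), without any of overexpressor libraries 1 to 3 (0.172, 0.14 and 0.176) and with DESeq2 size factors (0.0511), with 0.00946 the lowest. The enrichment of the SWEET family counts both SWEET10 and SWEET4 and was not recomputed without them. The iron transporter gene DMT1 fell 6.25-fold from 63 ± 5.2 to 10.1 ± 0.7 CPM (log2 -2.64, SE 0.14, adjusted p = 2.7e-07). LAR1 fell 8.34-fold (log2 -3.06, SE 0.15, adjusted p = 1.1e-07), and the drought-response regulator DREB1 fell from 48 ± 4.37 to 16.5 ± 2.22 CPM (log2 -1.54, SE 0.15, adjusted p = 5.5e-05).

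LOX2 (log2 1.66, SE 0.21, adjusted p = 6.4e-04) and LOX3 (log2 1.11, SE 0.14, adjusted p = 7.0e-04) rose in the GmNFYA overexpressor too. Another lipoxygenase gene, LOX9, fell from 1500 ± 93.7 to 907 ± 62.8 CPM (log2 -0.73, SE 0.14, adjusted p = 0.0194), and 2 of the 8 rose and 2 fell adjusted over the list alone. The LOX9 call ended without wild-type library 1 (0.0757), 2 (0.0694) or 3 (0.06) or overexpressor library 2 (0.108) or 3 (0.122), with 1.9e-07 the lowest adjusted p over the alternatives. HSP90A1 (log2 -2.88, SE 0.32, adjusted p = 2.0e-04) and HSP23.9 (log2 -1.66, SE 0.18, adjusted p = 1.3e-04) fell. HSP90A2 (log2 -1.0, adjusted p = 0.0216) and HSP18.5-C (log2 -1.44, adjusted p = 0.0153) fell as well, which made 4 of 14 tested genes with an HSP symbol (one-sided Fisher's exact test, adjusted p = 7.0e-04). The HSP90A2 call ended without wild-type library 2 or 3 (0.118 and 0.0986) or overexpressor library 1 or 2 (0.0856 and 0.0658), with 9.4e-04 the lowest adjusted p over the alternatives. The HSP18.5-C call ended without wild-type library 2 or 3 (0.0867 and 0.0523) or overexpressor library 1 (0.0538), with 5.8e-05 the lowest. The enrichment of this family counts both HSP90A2 and HSP18.5-C and was not recomputed without them. FAD2-1B did not pass at 232 ± 7.76 CPM (log2 0.32, adjusted p = 0.357), nor did P91 (log2 0.66, adjusted p = 0.443), P89 (log2 0.77, adjusted p = 0.317) or LEC1-B (log2 0.23, adjusted p = 0.535). SACPD-C stood at 86.9 ± 28.4 CPM against 188 ± 60.5 CPM (log2 -1.12, adjusted p = 0.067). It passed with the DESeq2 Wald test (0.00423) and without wild-type library 1 (log2 -1.36, adjusted p = 0.0236), and reached 0.247 without wild-type library 2. SNAP18, for a vesicle-trafficking protein, fell from 838 ± 145 to 299 ± 18.7 CPM (log2 -1.49, SE 0.21, adjusted p = 0.00177). WI12, for a wound-induced protein, fell from 56.1 ± 8.13 to 18.5 ± 1.78 CPM (log2 -1.60, SE 0.17, adjusted p = 1.4e-04). Both lie with Glyma.18G022400, which fell from 121 ± 8.81 to 39.7 ± 1.77 CPM (log2 -1.61, SE 0.13, adjusted p = 1.0e-05), in 17546 bp of chromosome 18 (1634531 to 1652076). Glyma.18G022551 (log2 -0.05, SE 0.55, adjusted p = 0.98) and Glyma.18G022600 (log2 -0.61, SE 0.24, adjusted p = 0.316), also tested in this span, did not pass. The 20 nearest flanking genes had a median log2 of -0.08 and a lowest of -0.46.

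**Figure D2:**
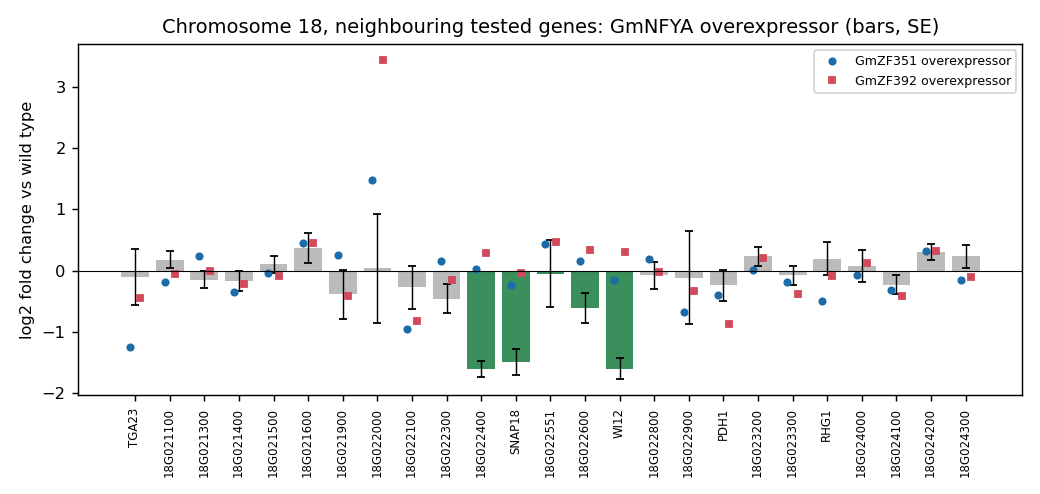
Log2 fold change against the wild type of neighbouring tested genes in their order on chromosome 18, with bars and SE for the GmNFYA overexpressor and points for the other overexpressors; green bars are the 5 tested genes of the run, 2 of them under 10 CPM, and grey bars the 20 flanking genes. In the GmNFYA overexpressor Glyma.18G022400, SNAP18 and WI12 lie from -1.61 to -1.49 and the flanking genes have a median of -0.08.

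By gene list, 8 lists were shifted in the GmNFYA overexpressor. Storage proteins were shifted up (median log2 0.81, 6 higher, 6 adjusted over the list alone; adjusted p = 1.3e-10, and adjusted p = 0.00216 with an estimated correlation). Late embryogenesis genes (median log2 0.39, adjusted p = 2.5e-04), fatty acid synthesis genes (12 members, median log2 0.18, adjusted p = 0.00327) and protease inhibitors (median log2 0.41, adjusted p = 0.00684) were shifted up. They gave adjusted p = 0.578, 0.128 and 0.557 with an estimated correlation. Shifted down were heat shock genes (median log2 -0.82, adjusted p = 1.1e-05), gibberellin genes (40 members, median log2 -0.25, adjusted p = 0.00327), sugar transport genes (27 members, median log2 -0.06, adjusted p = 0.00667) and aquaporins (35 members, median log2 -0.18, adjusted p = 0.0105). With an estimated correlation these gave adjusted p = 0.557, 0.557, 0.557 and 0.652. Among the sugar transport genes 5 fell, and 8 fell and 2 rose adjusted over the list alone. With exon-length offsets the gibberellin (median log2 -0.02, adjusted p = 0.496) and aquaporin (median log2 -0.07, adjusted p = 0.147) calls ended. Fatty acid synthesis (median log2 0.13, adjusted p = 0.0255) and sugar transport genes (adjusted p = 0.0455) still passed with them, but closer to the threshold. The other called lists had a lower adjusted p with offsets than without. Of the 6 fits that each leave out 1 library, 3 called aquaporins, 5 protease inhibitors and 6 the other lists.

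Against the wild type, 536 genes differed in the GmNFYA overexpressor, 331 higher and 205 lower, and 361 by 2-fold or more. The groups did not overlap for 21.9% of tested genes, where splits of 6 libraries average 10% by construction. The count was 355, 300 and 338 without wild-type library 1, 2 or 3, 300 and 335 without overexpressor library 2 or 3, and 829 with exon-length offsets.

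**Figure D3:**
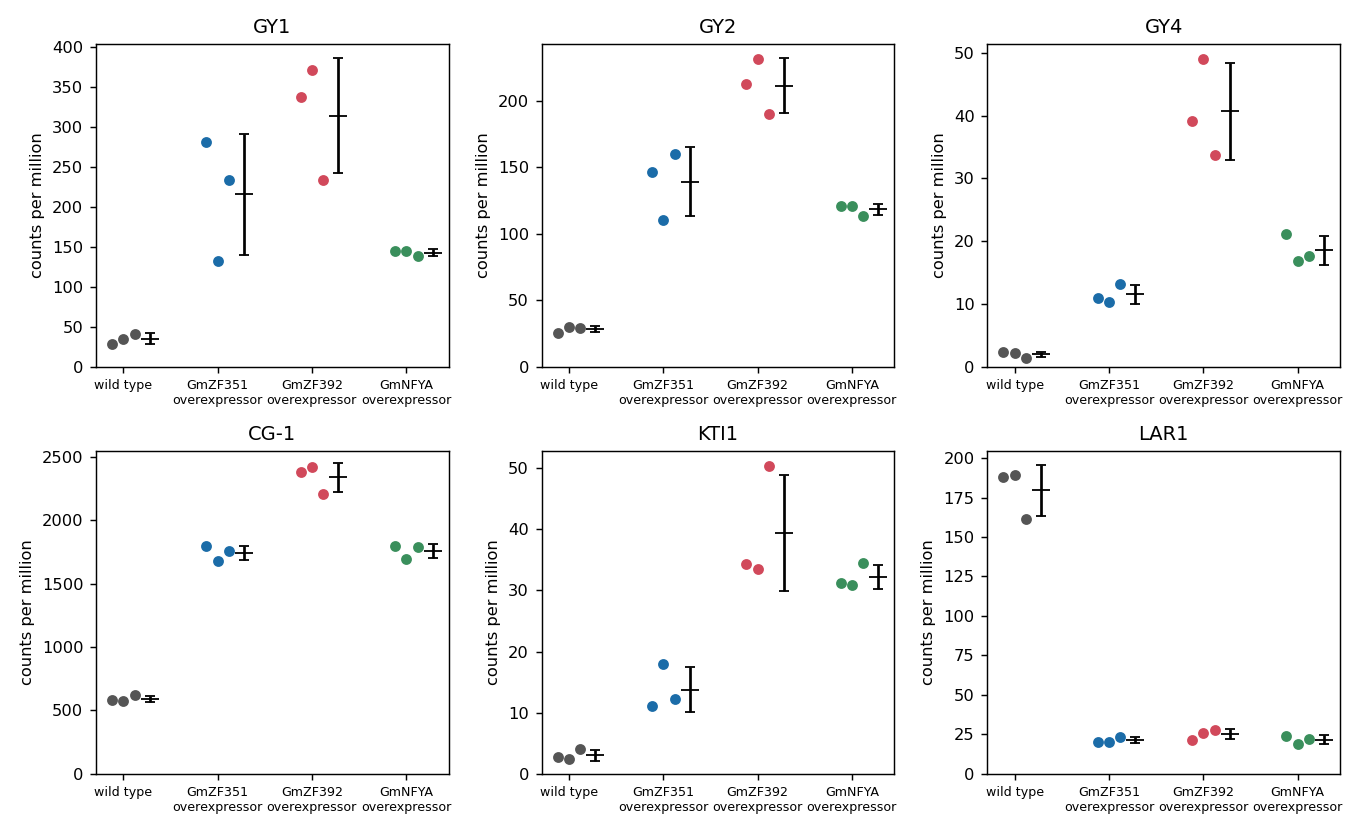
CPM (vertical axis, from 0) of 5 storage protein and protease inhibitor genes and of LAR1 in each genotype; each point is 1 library, with mean and SD beside the 3 points. CG-1 rises from 591 CPM in the wild type to 1740, 2340 and 1760 CPM in the GmZF351, GmZF392 and GmNFYA overexpressors, and LAR1 falls from 180 CPM to 21.3, 24.9 and 21.5 CPM.

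Other lists were not called against the wild type with the preset correlation and all 12 libraries. For desaturases (18 members) the median log2 change was 0.14, 0.08 and 0.07 in the GmZF351, GmZF392 and GmNFYA overexpressors (adjusted p = 0.656, 0.121 and 0.19). Triacylglycerol and oil body genes (7 members) gave medians of 0.06, 0.45 and 0.01 (adjusted p = 0.717, 0.171 and 0.68). Oil regulators (8 members) gave 0.06, 0.08 and 0.14 (adjusted p = 0.369, 0.606 and 0.0563). For NF-Y subunits (24 members) the adjusted p was 0.911, 0.641 and 0.68, and for flavonoid genes (32 members) 0.201, 0.171 and 0.172. It was for lignin genes (17 members) 0.717, 0.866 and 0.423, and for cell cycle genes (8 members) 0.317, 0.641 and 0.476. Jasmonate genes (9 members) gave 0.717, 0.171 and 0.72, and abscisic acid genes (9 members) 0.717, 0.492 and 0.0904. Auxin genes (35 members) gave 0.717, 0.606 and 0.476, and endoplasmic reticulum folding genes (6 members) 0.103, 0.0715 and 0.98. The lists called in some comparisons only did not pass in the others. Fatty acid synthesis gave adjusted p = 0.904 and 0.632 in the GmZF351 and GmZF392 overexpressors, sugar transport 0.717 and 0.866, gibberellin 0.384 and 0.866, and aquaporins 0.783 and 0.0736. Glycolysis gave 0.24 and lipoxygenases 0.196 in the GmNFYA overexpressor. Lipid breakdown gave 0.717 and 0.53 and cell wall genes 0.717 and 0.24 in the GmZF351 and GmNFYA overexpressors. Photosynthesis gave 0.979 and 0.518 and seed coat markers 0.121 and 0.331 in the GmZF392 and GmNFYA overexpressors. Pathogenesis-related and nodule genes had too few tested members for a list test (2 and 3). The test pointed against the sign of the median for jasmonate genes in the GmZF351 overexpressor, for photosynthesis, abscisic acid and gibberellin genes in the GmZF392 overexpressor and for seed coat markers in the GmNFYA overexpressor, all without a call. With exon-length offsets, oil regulators were called in the GmNFYA overexpressor (median log2 0.10, adjusted p = 0.0491, but adjusted p = 0.169 with an estimated correlation). Of the 6 fits that each leave out 1 library, 2 called oil regulators and 1 each abscisic acid and cell wall genes in that overexpressor. In the GmZF351 overexpressor 1 each called cell wall, endoplasmic reticulum folding, flavonoid and gibberellin genes, and in the GmZF392 overexpressor 1 each called aquaporins, endoplasmic reticulum folding and jasmonate genes.

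Between the overexpressors, VSPA stood at 29.8 ± 2.89 CPM in the GmZF351 overexpressor, 61.6 ± 6.83 CPM in the GmZF392 overexpressor and 118 ± 8 CPM in the GmNFYA overexpressor. It was higher in the last than in the GmZF351 overexpressor (log2 1.98, SE 0.14, adjusted p = 4.0e-06) and than in the GmZF392 overexpressor (log2 0.94, SE 0.13, adjusted p = 0.00176). SWEET16 was higher in the GmNFYA overexpressor (15.3 ± 0.881 CPM) than in the GmZF351 overexpressor (3.28 ± 0.442 CPM; log2 2.22, SE 0.17, adjusted p = 1.6e-05) and the GmZF392 overexpressor (log2 1.62, SE 0.17, adjusted p = 1.4e-04). SWEET21 (log2 -2.14, SE 0.14, adjusted p = 3.2e-06) and SWEET11 (log2 -1.60, SE 0.15, adjusted p = 6.4e-05) were lower in the GmNFYA than in the GmZF351 overexpressor. DMT1 was lower in the GmNFYA overexpressor than in the GmZF351 (log2 -3.35, SE 0.15, adjusted p = 3.2e-08) and GmZF392 overexpressors (log2 -3.0, SE 0.15, adjusted p = 1.2e-07). GASA26, of a gibberellin-regulated family, stood at 26.1 ± 4.31 CPM in the GmZF392 overexpressor, higher than in the GmZF351 overexpressor (7.33 ± 0.228 CPM; log2 1.83, SE 0.17, adjusted p = 1.7e-04). It was lower in the GmNFYA than in the GmZF392 overexpressor (log2 -2.44, SE 0.18, adjusted p = 5.3e-06). GH3 was higher in the GmZF392 than in the GmZF351 overexpressor (log2 2.24, SE 0.27, adjusted p = 0.00101) and lower in the GmNFYA than in the GmZF392 overexpressor (log2 -2.13, SE 0.26, adjusted p = 7.0e-04). GY4 was higher in the GmZF392 than in the GmZF351 overexpressor (log2 1.82, SE 0.18, adjusted p = 2.9e-04). HPS, for a hydrophobic protein of the seed surface, was lower in the GmZF351 overexpressor (99.1 ± 31.7 CPM) than in the GmZF392 (303 ± 68.4 CPM, adjusted p = 0.00362) and GmNFYA overexpressors (370 ± 35.2 CPM, adjusted p = 6.9e-04).

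The storage protein list was higher in the GmZF392 than in the GmZF351 overexpressor (median log2 0.42, adjusted p = 0.00935, but adjusted p = 0.187 with an estimated correlation). It was lower in the GmNFYA than in the GmZF392 overexpressor (median log2 -0.71, adjusted p = 7.7e-08, and adjusted p = 0.00617 with an estimated correlation). Between the GmZF392 and GmZF351 overexpressors 137 genes differed, 122 higher and 15 lower in the former. The count was 77 and 64 without GmZF351 overexpressor library 1 or 3, 86 and 90 without GmZF392 overexpressor library 1 or 3, and 266 with exon-length offsets. Between the GmNFYA and GmZF351 overexpressors 376 genes differed, 203 higher and 173 lower in the former. The count was 224 and 180 without GmZF351 overexpressor library 2 or 3, 205, 163 and 188 without GmNFYA overexpressor library 1, 2 or 3, and 768 with exon-length offsets. Between the GmNFYA and GmZF392 overexpressors 364 genes differed, 90 higher and 274 lower in the former. The count was 235 without GmZF392 overexpressor library 3, 198 and 207 without GmNFYA overexpressor library 2 or 3, and 562 with exon-length offsets. Photosynthesis genes were higher in the GmZF392 than in the GmZF351 overexpressor (median log2 0.24, adjusted p = 0.00681, but adjusted p = 0.501 with an estimated correlation). Gibberellin genes were lower in the GmNFYA than in the GmZF351 overexpressor (median log2 -0.32, adjusted p = 2.0e-04, but adjusted p = 0.614 with an estimated correlation). Against the GmZF351 overexpressor the GmNFYA overexpressor also had higher fatty acid synthesis genes (median log2 0.25, adjusted p = 0.00444) and lower lipoxygenases (-0.36, 0.0204), with adjusted p = 0.203 and 0.614 with an estimated correlation. Against the GmZF392 overexpressor it had lower sugar transport (median log2 -0.29, adjusted p = 0.00212), gibberellin (-0.20, 0.00332), lipoxygenase (-0.34, 0.00886) and protease inhibitor genes (-0.29, 0.0373) and higher fatty acid synthesis genes (0.20, 0.0157). These gave adjusted p = 0.522, 0.552, 0.552, 0.552 and 0.251 with an estimated correlation. With exon-length offsets the gibberellin call against the GmZF351 overexpressor ended (median log2 -0.14, adjusted p = 0.0954). The other list calls between overexpressors passed with them, as did photosynthesis (adjusted p = 0.00136) and auxin genes (0.0181) in the GmNFYA against the GmZF351 overexpressor. Against the GmZF392 overexpressor auxin (0.0313) and lipid breakdown genes (0.0387) also passed. Of all these, storage proteins in the GmNFYA against the GmZF392 overexpressor passed with an estimated correlation too (0.00724). The groups did not overlap for 14.8%, 17.9% and 17.5% of tested genes in these 3 comparisons. Splits of 6 libraries average 10% by construction and single splits can differ from it, so the excess is not a test of genotype.

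Across the 4 genotypes, 1152 genes (3.36% of those tested) differed in the overall test, 745 without wild-type library 2 and 1923 with exon-length offsets. Against the wild type, 225 genes were called in all 3 overexpressors, 167 of them higher in each, such as GY1, GY2, GY4, CG-1, KTI1, LOX2 and LOX3, and 56 lower in each, such as LAR1, HSP90A1 and HSP23.9. The other 2 differed in direction: Glyma.01G131100 rose in the GmZF351 and GmZF392 overexpressors and fell in the GmNFYA overexpressor, and Glyma.15G199600 fell in the GmZF351 overexpressor and rose in the others. The call of Glyma.01G131100 in the GmZF351 overexpressor ended without wild-type library 2 (0.0539) or 3 (0.0562). The call of Glyma.15G199600 ended in the GmZF351 overexpressor without wild-type library 1 (0.0647) or overexpressor library 3 (0.081) and with exon-length offsets (0.0592), and in the GmZF392 overexpressor without wild-type library 2 (0.0751) or 3 (0.0646) or overexpressor library 1 (0.0664).

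Called in 1 overexpressor alone were 312 genes for GmZF351, 289 for GmZF392 and 202 for GmNFYA; these counts do not test whether the effects differ. Fold changes against the wild type covaried across genes by 0.121 for GmZF351 and GmZF392, 0.097 for GmZF351 and GmNFYA and 0.115 for GmZF392 and GmNFYA. Simulated unchanged groups against a shared simulated wild type gave a mean of 0.0396, 0.0395 and 0.0396. All libraries, wild type included, were redrawn with each gene independent, so the simulations hold no length trend or correlation between genes. They cannot tell how much of the covariance comes from these. Without the 45 genes that differ by a log2 of 3 or more in all 3 overexpressors the covariances were 0.095, 0.0722 and 0.09. The correlations were 0.63, 0.53 and 0.58 (0.57, 0.46 and 0.52 without those genes), against 0.50 in each simulation. Fold changes had the same sign for 66%, 62.1% and 68.9% of genes, against 66.7%, 66.6% and 66.7% in the simulations, so the higher covariance was not matched by more genes of the same sign in the pairs with GmZF351. The 3 wild-type libraries are shared and too few to be divided between the comparisons, so part of the covariance can come from them. Called in the same direction for these pairs were 263, 187 and 220 genes higher and 127, 69 and 69 lower. Expected numbers that assume independent comparisons are not set against these counts, since the comparisons share the wild-type libraries. In the simulations, with their shared redrawn wild type, a mean of 0.05, 0.1 and 0.05 genes were called in both comparisons of a pair. No simulation gave more than 1, with the limits of the simulations given above.

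Among the shared genes, 45 differed by a log2 of 3 or more in the same direction in all 3 overexpressors, 24 higher and 21 lower, and 1 of the 45 also differed between overexpressors. Glyma.13G027800 (chromosome 13) rose from 1.02 CPM in the wild type to 53.3, 59.8 and 50.5 CPM in the GmZF351, GmZF392 and GmNFYA overexpressors, and Glyma.16G206100 (chromosome 16) fell from 138 ± 13.2 CPM to 8.54, 6.43 and 5.11 CPM. Of the 45, 2 have a symbol, the receptor-like kinase genes CRK48 and CRK62. CRK48 rose from 0.0327 to 1.31, 1.5 and 0.992 CPM (the GmNFYA call ended without wild-type library 2, adjusted p = 0.0508) and CRK62 from 0.0531 to 1.15, 1.13 and 1.19 CPM, with wild-type values under the level that a count of 0 allows. No fragment was counted in the wild type for 7 of the 45 genes, and none in at least 1 overexpressor group for 14. Of the 44 on numbered chromosomes, 27 lay within 1 Mb of another of them, against a median of 6 in 10000 random sets of tested genes (permutation p = 1.0e-04, the smallest these can give), and 14 lay on chromosome 18, which holds 4.9% of the tested genes. The random sets were matched neither for expression nor for gene family, so the p does not show what draws these genes together.

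**Figure D4:**
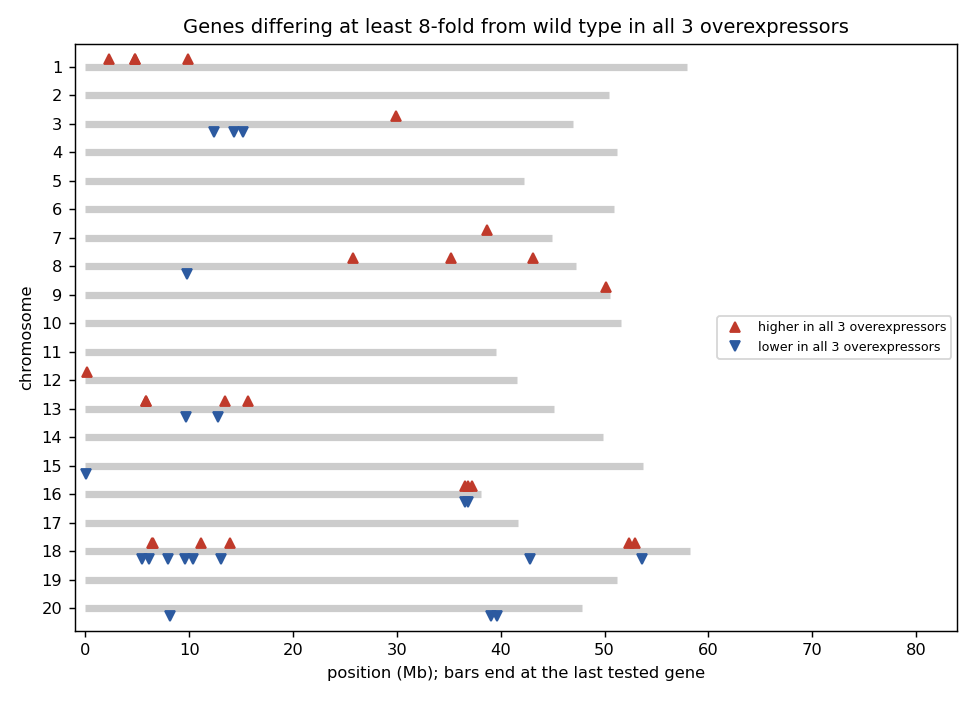
Position in Mb (horizontal axis) on each chromosome (vertical axis) of the genes with a log2 fold change of 3 or more in all 3 overexpressors against the wild type; triangles above the bars are the 24 higher genes and those below the 20 lower genes. Chromosome 18 holds 14 of the 44 genes and chromosome 13 holds 6.

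Libraries also differed along a trend with exon length, both within genotypes and in part between them. The first principal component held 29.4% of the variance, and its loadings correlated with exon length across 28504 genes (Spearman's rho 0.70; genes are not independent replicates). The correlation of a library's deviations with exon length ran from -0.62 in GmZF351 overexpressor library 2 to 0.62 in GmNFYA overexpressor library 1, with wild-type libraries at -0.06, -0.48 and -0.01. The median log2 fold change in the fifth of genes with the shortest exons (up to 1243 bp) and in the fifth with the longest (from 3192 bp) was 0.04 and 0.02 in the GmZF351 overexpressor, -0.11 and 0.09 in the GmZF392 overexpressor and -0.21 and 0.18 in the GmNFYA overexpressor. Storage proteins kept medians of 1.57, 1.32 and 0.86 with exon-length offsets (adjusted p = 7.6e-04, 3.7e-04 and 0.0015 with an estimated correlation). Protease inhibitors passed with an estimated correlation as well once the trend was removed (adjusted p = 0.00326, 0.00388 and 0.00943), and late embryogenesis genes had medians of 0.78, 0.56 and 0.59.

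**Figure D5:**
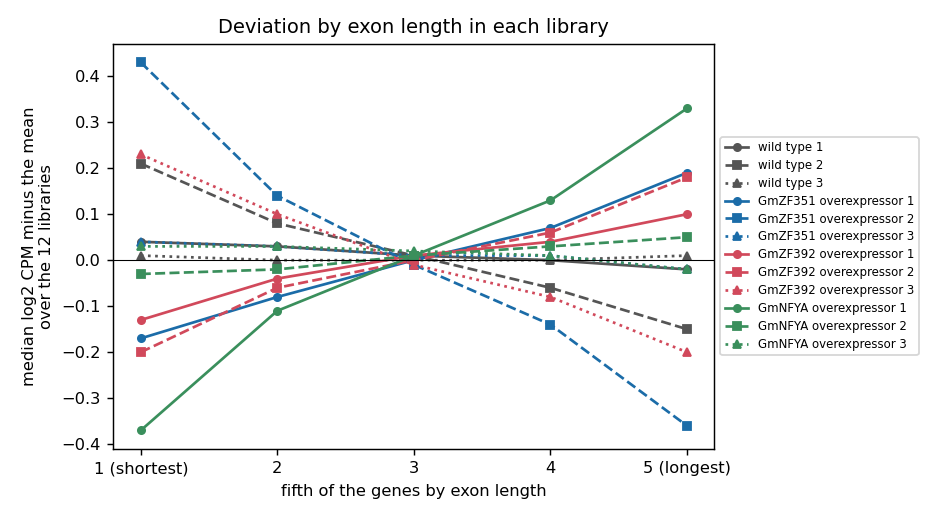
Median deviation of log2 CPM from the mean of the 12 libraries (vertical axis) in 5 classes of genes by exon length (horizontal axis, shortest to longest), 1 line per library, coloured by genotype. In the class with the shortest exons GmZF351 overexpressor library 2 lies at 0.43 and GmNFYA overexpressor library 1 at -0.37, and in the class with the longest at -0.36 and 0.33.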

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

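The alternatives with exon-length offsets, those without both libraries at the ends of the length trend, those without the genes that differ by a log2 of 3 or more in all 3 overexpressors, and the left-out libraries of the test over 4 genotypes were chosen after the result was seen. Counts of differing genes are given in the order GmZF351, GmZF392 and GmNFYA overexpressors against the wild type, then GmZF392 against GmZF351, GmNFYA against GmZF351 and GmNFYA against GmZF392. They moved by over 1.5 times with exon-length offsets (1329, 1192, 829, 266, 768 and 562, and 1923 over 4 genotypes), the DESeq2 Wald test (1231, 1135, 954, 342, 905 and 662) and a threshold of 0.01 (310, 409, 264, 69, 151 and 201). With only the 6 libraries compared they moved for GmZF351 (368), GmZF392 against GmZF351 (69) and GmNFYA against GmZF351 (123), and without both end libraries for the last (175). With an estimated correlation 1 list was called in each comparison with the wild type and for GmNFYA against GmZF392, and 0 for GmZF392 against GmZF351 and GmNFYA against GmZF351, and with exon-length offsets 4 for GmZF392; the cause was not tested. Leaving out 1 library gave 392 to 575, 448 to 606, 300 to 385, 64 to 112, 163 to 368 and 198 to 273 genes, 745 to 1156 over 4 genotypes, and 8 to 10, 3 to 10 and 7 to 9 lists. Covariances then ran from 0.115 to 0.145 (GmZF351 and GmZF392), 0.0794 to 0.131 (GmZF351 and GmNFYA) and 0.101 to 0.145 (GmZF392 and GmNFYA), and fell to 0.095, 0.0722 and 0.09 without the genes that differ by a log2 of 3 or more. The log2 changes of GmZF351, GmZF392 and GmNFYA in their overexpressors ran from 5.60 to 5.72, 3.11 to 3.32 and 2.83 to 2.98, and that of GmZF351 in the GmZF392 overexpressor from 1.05 to 1.17. A replicate block gave 645, 659, 510, 117, 350 and 326 genes and 1025 over 4 genotypes. Uncalled genes that changed sign were SACPD-C in the GmZF351 overexpressor (log2 -0.15 to 0.27; -0.15 without wild-type library 1, -0.03 without overexpressor library 2) and LEC1-A. LEC1-A turned in the GmZF351 overexpressor without overexpressor library 2 (-0.04, up to 0.27), in the GmZF392 overexpressor without wild-type library 1 (-0.10, up to 0.14) or overexpressor library 3 (-0.07), and in the GmNFYA overexpressor without wild-type library 1 (-0.06, up to 0.20) or overexpressor library 2 (-0.01) or 3 (-0.04). The cause was not tested. Of 147 gene and comparison pairs, 144 kept direction and side of the threshold with the DESeq2 Wald test, 146 with DESeq2 size factors and 144 with exon-length offsets. Without 1 library 765 of 882 values did, 108 lost the call (27 pairs), 1 gained it and 8 turned. Upper-quartile factors, both other filters and limma-voom kept each count within 1.5 times. Depth limits genes below a floor of 0.132 to 0.168 CPM.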

Other observations

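Chosen after the result was seen were the tests of genomic segments, of counts near the floor, of a later seed stage and of fewer copies, and all values with exon-length offsets.

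Of 26 clock genes, 3 fell in each of the zinc finger overexpressors. PRR3A, a pseudo-response regulator, fell in the GmZF351 (log2 -1.62, SE 0.20, adjusted p = 5.9e-04) and GmZF392 overexpressors (log2 -1.66, SE 0.20, adjusted p = 3.4e-04). E2, the GIGANTEA homolog behind a maturity locus, fell from 45.9 to 17.8 CPM in the GmZF351 overexpressor (log2 -1.37, SE 0.20, adjusted p = 0.0021) and by a log2 of -1.07 in the GmZF392 overexpressor (SE 0.20, adjusted p = 0.00922). PRR3B fell in the GmZF392 overexpressor (log2 -1.07, SE 0.19, adjusted p = 0.00821) and in the GmZF351 overexpressor (log2 -0.85, adjusted p = 0.0376). In the latter its call ended without wild-type library 1 (0.127), 2 (0.0743) or 3 (0.129) or overexpressor library 2 (0.114) or 3 (0.118). The clock list as a whole was not called (median log2 0.01, 0.07 and -0.06, adjusted p = 0.911, 0.866 and 0.242; the test pointed down in both zinc finger overexpressors against the sign of the median). With exon-length offsets it was called lower in the GmNFYA overexpressor (median log2 -0.09, adjusted p = 0.0338, but adjusted p = 0.169 with an estimated correlation), with 5 genes lower and 1 higher. The time of harvest is not given in the sources used here.

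Of the 45 genes that differ by a log2 of 3 or more in the same direction in all 3 overexpressors, 44 lie on numbered chromosomes, and 27 of these have another within 1 Mb, against at most 22 in 10000 random sets, in 10 runs of which 6 hold genes of both directions. A single aberrant wild-type library is argued against, since at least 33 of the 45 were still called in all 3 comparisons without any 1 wild-type library. Counts near the floor cannot be told apart for the set as a whole: the median CPM in the higher group was 2.27, but the filter and the choice of these genes largely fix that level. A candidate explanation is that the wild-type seeds and the 3 lines differ in genomic segments, for example through the seed stock that was transformed, which would separate these genes from the overexpressed ones. The labels give no pedigree, RNA counts do not show DNA, and the random sets were matched neither for expression nor for gene family.

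The storage protein list was shifted up in all 3 overexpressors. The length trend between libraries is argued against as the whole source, since the lowest of the 3 list medians with exon-length offsets was 0.86. The overexpressor seeds may also have been at a later stage than the wild-type seeds, and this cannot be told apart from an effect of the genes: late embryogenesis genes had medians of at least 0.56 with exon-length offsets, but adjusted p = 0.161, 0.228 and 0.143 with an estimated correlation. Without offsets the mean deviation of the late embryogenesis genes was -0.84, -0.12 and -0.29 in the wild-type libraries. GmNFYA overexpressor library 1 lay among these at -0.35, and the other overexpressor libraries lay above them at -0.03 to 0.55. The labels give the same stage for all libraries. The genotype is the biological difference that the design names, and an effect of it stays open as a hypothesis; no test here separates it from stage or line background.

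The run on chromosome 18 was lower in the GmNFYA overexpressor alone, by a median of 3.03-fold over its 3 genes with 10 CPM or more. The length trend is argued against, since their median log2 change was -1.40 with exon-length offsets. SNAP18 and WI12 lie in a segment known to be repeated in some soybean lines, and a candidate explanation is fewer copies of it in the GmNFYA line: the log2 changes of the 3 genes lie within 0.12 of each other, less than their largest SE of 0.21, but with exon-length offsets they spread further (-1.63, -1.37 and -1.40). The remaining 2 tested genes of the run, under 10 CPM, moved less (log2 -0.05, SE 0.55, and -0.61, SE 0.24, neither called). A common factor over the run explains neither, less clearly so for the former, which has the wider SE and stood at 1.81 CPM in the wild type. Copies were not counted in DNA, and a cis-acting change over the run stays open.

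For each pair of genotypes the 10 splits of 6 libraries are too few for a share under 0.05. The real split called 744, 752 and 536 genes for the GmZF351, GmZF392 and GmNFYA overexpressors against the wild type, 137 for GmZF392 against GmZF351, 376 for GmNFYA against GmZF351 and 364 for GmNFYA against GmZF392. In each case 1 of the 10 splits, the real one, called as many, and the highest other split called 0 with edgeR. At an unadjusted p under 0.05 the other splits gave 471 to 3295, 381 to 2860, 209 to 2306, 405 to 8636, 249 to 5094 and 333 to 5443 genes, against 4050, 4044, 4003, 3290, 4328 and 3484 for the real ones. The split with 8636 genes sets GmZF351 overexpressor library 1 and GmZF392 overexpressor libraries 1 and 2 against the rest, which follows the length trend and points to that structure among the libraries. For the test over 4 genotypes 60 splits were used, fewer than planned. Of these 1, the real one, called as many as 1152 genes, a share under 0.05, and the highest other called 844. The labels do not say whether each library came from a separate plant. The share therefore shows that libraries of a genotype resemble each other, and it cannot exclude chance differences between plants. At an unadjusted p under 0.05 the share of splits was not under 0.05. The real split gave 5014 genes and the others 67 to 5901, and 3 of 60, the real one included, gave as many.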
